A study of Mus musculus with 7 samples.

How the data were processed

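The data are droplet-based single-cell RNA libraries of the mouse submandibular gland at E12, E14, E16, P1, P30 (females and males) and in adults, with 1 library in each of 7 groups. Per the labels, glands of littermates were pooled, the first 6 libraries are of ICR mice and the adult library is of C3H mice, and tissue was dissociated in different ways by age. The deposited matrices hold raw UMI counts per gene and barcode, whole numbers to which no normalization had been applied before deposit, and the authors had already filtered the barcodes. The authors' notes name Cell Ranger 2.0.0 and 3.0.1, Seurat 2 and 3 and the genome build mm10 without saying which served which library; the adult file header names Cell Ranger 3.0.1. Each matrix was deposited in 2 copies, which differed in 0 entries, and 1 copy was used. All files list the same 48816 genes, of which 41341 match GENCODE mouse release 21 with the version of the identifier and 48349 without it.

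Barcodes numbered 5898 at E12, 6432 at E14, 8000 at E16, 3557 at P1, 1000 in each P30 library and 3648 in adults. Whether the authors set the round numbers at E16 and P30 is not given in the sources used here, and the shares of cells in these libraries depend on which barcodes were kept. Barcodes with at least 200 detected genes and at most 10% mitochondrial counts were kept. Doublets were ranked by the share of simulated doublets among nearest neighbours, with 2 simulated doublets per cell, and the highest were removed at an assumed rate of 0.8% per 1000 cells. This took out 278 cells at E12, 328 at E14, 244 at E16, 98 at P1, 3 in each P30 library and 43 in adults. Each library was clustered alone: counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen, and 30 principal components and 15 nearest neighbours went into Leiden clustering at resolution 1. This gave 22, 22, 27, 20, 13, 13 and 18 clusters from E12 to adults. Clusters were named from marker lists of 17 cell classes, the immune types being pooled into 1 class. A marker was counted in a cluster where at least 25% of the cells held it, and a cluster had to have at least 3 such markers and to be led by markers of its own class. A cluster led by more markers of another class was first given that class, where its score for that class was high enough. Clusters that then still failed a rule, or had few UMIs and no own marker among their top genes, stayed unnamed. These held 690 cells at E12, 831 at E14, 738 at E16, 16 in P30 males and 21 in adults.

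Comparisons were planned for the epithelium and the mesenchyme, and the other classes were not compared. Where the class had at least 50 cells in both libraries, counts were summed over the cells and scaled to counts per 1000000 (CPM). This left 7 comparisons in epithelium and 3 in mesenchyme; mesenchyme had under 50 cells in the P30 and adult libraries, so its later comparisons were left out. The log2 ratio of CPM was taken for genes with at least 50 CPM in one of the sums and at least 20 counts over both, with counts of 0 set to a floor of 3 counts in the sum. Intervals are exact 95% Poisson intervals (conditional binomial), and for a count of 0 they allow smaller changes than a fold taken at the floor. With 1 library per group no test between groups was made, and no paired analysis was possible because no animal links the libraries. The text names, per comparison, the 10 genes with the largest rise and the 10 with the largest fall, and up to 4 members of each gene list, of which the report gives a part. Left out of the ranking were mitochondrial, ribosomal protein, globin and predicted genes, and genes over 3 times higher in another class of the library where they were higher. A list member counts as higher or lower where the change is at least 2-fold and the interval excludes no change. A member far below 50 CPM in one sum enters only if it is higher in the other, so its direction follows from this filter.

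The 16 gene lists were compared through the median log2 ratio of their expressed members, with the order-statistic interval over members, and set against 10000 random lists matched on expression in 20 bins. Shares of cells have exact binomial intervals, which are printed for the epithelial shares. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, in epithelium and in a class that should lack the gene; at P30, where mesenchyme and endothelium had too few cells, immune cells served instead. Globin shares used the erythroid class where it had at least 20 cells and all cells otherwise. To find genes whose reads cannot be told from those of near-identical copies, the last 400 bases of each gene's transcripts were searched for words of 31 bases found in other genes.

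Gene lists, markers, cell and gene filters, comparisons and the rule for naming genes were fixed before the data were examined. The rule that turns marker scores into class names with its thresholds, the search for shared sequence, the use of immune cells as a background class, the choice which of the named genes the report gives, and the counting interval used for a list with 1 expressed member were set afterwards. Alternatives planned in advance were a minimum of 500 genes, a limit of 20% mitochondrial counts, no doublet removal, resolution 0.5, scaling by the trimmed mean of M values (TMM), equal weight for every cell, no CPM minimum, and thinning to 1500 UMIs or not at all. Counting unnamed clusters in their best-scoring class, and taking every barcode with over 50% globin counts for the globin shares, were added after seeing the data.

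The steps were tested on simulated data. For epithelium from E14 to E16, 2823 genes were simulated, 200 of them changed. The interval covered the true value for 95.24% of 2624 unchanged genes, 89.8% of 49 genes changed by 1.2 on the log2 scale, 94% of 50 changed by 2, all of 50 changed by 4 and 96% of 50 changed by 8, and the direction was called right for 100% at each size. Of 100 random lists, 5 lay outside the middle 95%, and a raised list of 15 genes reached percentile 100. The counts were Poisson draws, which the intervals assume, and the random lists came from the same genes as their reference. These values therefore check the calculation only. They hold no variation between cells, animals or libraries, so they do not show that the intervals cover it. In a simulated E16 library of 1470 cells, 66 of 70 doublets were found and 1396 of 1396 single cells were named right. These cells were drawn from the sums of the epithelium, mesenchyme and endothelium classes, with no variation within a class. Each doublet joined different classes, and as many cells were removed as there were doublets. The real E16 library is less simple and left 738 cells unnamed, so these values do not measure how well real cells were named.

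Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM. The random seed was 1.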

Results

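RNA of single cells from the mouse submandibular gland, a large salivary gland of the lower jaw, was counted by droplet-based sequencing with unique molecular identifiers (UMIs). The libraries covered E12, E14, E16, P1, P30 females, P30 males and adults, where E is the day of gestation and P the day after birth. Each of the 7 groups had 1 library, so there were no replicates and no test between groups. Intervals of shares and of single genes below cover counting error only. Intervals of list medians follow the spread between the member genes, and none covers the variation between animals. Glands of several littermates were pooled, the first 6 libraries came from ICR mice and the Adult library from C3H mice. The total was 54294428 UMIs at E12, 69279580 at E14, 55135169 at E16 and 45455935 at P1, against 15991437 in P30 females, 12896764 in P30 males and 22107882 in adults. The median per barcode was 7036 UMIs at E12, 8169.5 at E14, 5823 at E16, 10707 at P1, 5956.5 in P30 females, 5475.5 in P30 males and 1573 in adults. After filtering, 5617, 6073, 5282, 3402, 621, 600 and 2285 cells were kept in the same order.

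The first question was how the cell classes of the gland changed with age. Epithelium was 9.10% of the E12 cells (95% exact binomial interval 8.36 to 9.88), 45.99% at E14 (44.7 to 47.3), 15.9% at E16 (14.9 to 16.9) and 85.1% at P1 (83.9 to 86.3). It was 77.9% in P30 females (74.5 to 81.1), 66.7% in P30 males (62.7 to 70.4) and 83.1% in adults (81.5 to 84.6). Mesenchyme, the loose connective tissue around the branching epithelium, was 71.6% of cells at E12, 30.3% at E14, 41.6% at E16 and 12.3% at P1. Erythroid cells reached 14.1% at E16, immune cells were 16.9% of the P30 female and 24.5% of the P30 male cells, and endothelium was 9.02% of the adult cells. Before filtering, 39.98% of the E16 barcodes held mostly globin counts, many of them with under 200 genes, so the erythroid share depends on that minimum. Neurons (2.26%) and skeletal muscle cells (2.08%) were seen at E12, and glia (1.98%) at E14. Tissue was dissociated in 3 ways, with papain alone at E12 and E14, with more enzymes and filters at E16 and P1, and with a tumour dissociation kit later, so shares across these steps mix age with yield.

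**Figure D1:**
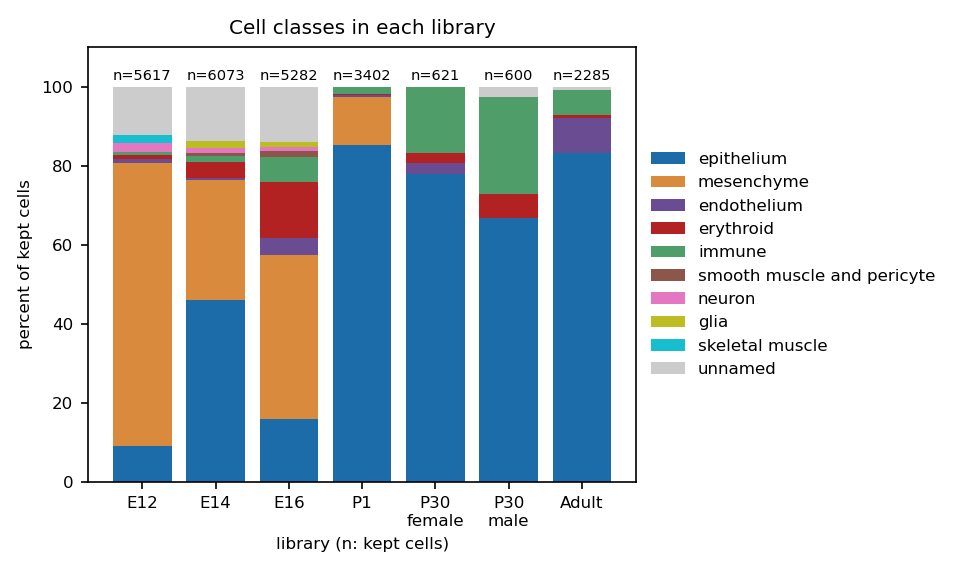
Percent of the kept cells of each library (vertical axis, from 0 to 100) in each cell class (colours), with the 7 libraries along the horizontal axis. The epithelial part grows from 9.10% at E12 to 85.1% at P1, with a step down to 15.9% at E16.

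From E12 to E14, when the epithelial bud branches, single salivary and duct genes rose in the epithelium and basal genes such as Krt5 fell. Dcpp1, a demilune and parotid protein of saliva (ENSMUSG00000096445.1, mm10 chromosome 17, 23880876 to 23882853), rose from 0 counts to 182 CPM (the count of a gene in the class, scaled to a total of 1000000), 581-fold with the 0 set to 3 counts. Wfdc18, of the whey acidic protein family, rose by 9.01 on the log2 scale (interval 7.65 to 10.88), and the duct transcription factor gene Tfcp2l1 by 6.20. Of 12 duct keratin and junction genes, 3 were higher and 4 lower, Cldn6 among the latter (median 0.73, -1.17 to 2.04), against 6 and 2 with TMM scaling (trimmed mean of M values). Keratin genes moved apart, with Krt23 up by 4.15 and Krt17 up by 3.27, while the basal keratin gene Krt5 fell by 3.56 and Krt15 fell by 2.25. The BMP targets Id1 and Id3, inhibitors of helix-loop-helix factors, fell by 4.37 and 3.12, and the ligand genes Tgfb2 and Wnt6 fell by 3.09 and 2.55. Of 8 expressed members of the basal epithelium list, 5 were lower and 2 higher (median log2 ratio -1.14), with 3 lower under TMM. The end bud regulators had a median of -0.70 (interval -1.42 to 0.39), with Sox11 and Hmga2 as the 2 lower members of 11. None of 23 cell cycle genes changed by 2-fold (median 0.06), and 5 of 12 genes of the imprinted growth network were lower, among them Nnat, which fell by 2.15, while the other 4 (Mest, H19, Igf2 and Plagl1) were over 3 times higher in another class of the E12 library. Of 6 growth factor genes, Tgfb2 and Wnt6 were the 2 lower and Nrtn the 1 higher. Nrtn, which encodes neurturin, the ligand that draws in parasympathetic neurons, rose by 1.69. The sums came from 511 and 2793 cells, the median gene moved by -0.02, and TMM scaling would add 0.27 to each log2 ratio. Dcpp1 shares 44.9% of its 3' sequence with other genes, so its own count is uncertain.

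From E14 to E16, salivary product genes rose. Bpifa2 (parotid secretory protein, chromosome 2, 154008265 to 154016079) rose from 3 to 17888 counts, a log2 ratio of 14.84 (13.29 to 17.12). Smgc (submandibular gland protein C, ENSMUSG00000047295.16, chromosome 15, 91838265 to 91861438) rose from 7 to 13630 counts (log2 13.22, 12.18 to 14.54). Muc19, a gel-forming mucin gene whose span (91838326 to 91934555) overlaps that of Smgc, rose by 10.56. All 7 expressed secretory products were higher, with a median log2 ratio of 8.45 (3.36 to 14.84), among them Pip by 8.45, the lactoperoxidase gene Lpo by 6.04 and the water channel gene Aqp5 by 5.55. Members far below 50 CPM at E14, such as Bpifa2 and Smgc, entered only through their E16 level, so their direction follows from this filter. Spdef and Creb3l1, transcription factor genes of secretory cells, rose by 7.27 and 4.51, and 5 of 13 secretory machinery genes were higher and 0 lower (median 0.51), against 4 and 2 with TMM. Duct genes rose as well, 10 of 13 duct keratin and junction genes being higher (median 1.48), with Krt7 up by 2.85, Krt19 by 2.58 and Wfdc2 by 2.47. Of 5 duct ion transport genes, 4 were higher (median 1.66), such as Atp1b1 of the sodium pump and the potassium channel gene Kcnn4.

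On the falling side from E14 to E16, 5 of 11 end bud regulators were lower and 1 higher (median -0.43, -2.19 to 0.45), among them the FGF target genes Etv4 and Etv5, which fell by 2.19 and 1.51, and Hmga2, which fell by 4.34. The collagen gene Col2a1 went from 2389 counts to 1 (log2 -8.93, -14.23 to -6.45; -7.47 with equal cell weight). The histone genes Hist1h2ap and Hist1h2ae fell by 5.87 and 4.74, and the glycolysis genes Pgk1 and Eno1 fell by 3.56 and 3.11, but these 4 genes share 41.7% to 100% of their 3' sequence with other genes and are uncertain. The cell cycle list had a median of -0.33 with 1 of 25 genes higher, Pcna. Of 16 genes of the dissociation stress list, 9 were higher, including Zfp36 and Nr4a1, and 2 lower (median 1.11), across the change of dissociation enzymes, though Fosb, Socs3 and Jund among these were over 3 times higher in another class. In mesenchyme over the same step, 4 of 17 stress genes were lower and 1 higher. From E12 to E14, both with papain alone, 8 of 16 were higher in mesenchyme. Whether the enzymes play a part was not tested. The sums came from 2793 and 840 cells, the median gene moved by -0.15 and TMM scaling would subtract a similar amount (-0.15).

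From E16 to P1, salivary protein genes rose steeply in the epithelium and cell cycle and contractile genes fell. Bpifa2 rose by 5.72 to 109730 CPM and Smgc by 5.46 to 69980 CPM. The largest rises were Car6, a secreted carbonic anhydrase gene, by 13.43 (12.31 to 14.87), the mucin-like gene Prol1 by 12.47, the secretoglobin gene Scgb1b27 by 12.32 and the mucin-like gene Mucl2 by 11.71. Mucl1 and the proline-rich protein gene Prb1 rose from 0 counts, 1687-fold and 412-fold with the 0 set to 3 counts. Of 14 secretory products, 11 were higher and 1, Muc19, was lower, with a median of 5.59 (0.77 to 12.32). The endoplasmic reticulum genes Herpud1, Tmed3 and Ssr4 rose by 1.87, 1.52 and 1.38, and Pdia4 fell by 1.72 (-0.99 with TMM). These were the 3 higher and the 1 lower of 16 secretory machinery genes (median 0.48). With TMM, 13 were higher and 0 lower (median 1.21), so this count depends on the scaling. The cell cycle list fell by 1.76 in its median (-2.05 to -1.48), with 19 of 20 genes lower, against 12 of 20 and a median of -1.03 with TMM. All 5 myoepithelial contractile genes were lower (median -2.67), Acta2 among them, as were 4 of 6 basal genes (median -1.41, with TMM 2 of 6 and -0.68) and 3 of 3 basement membrane genes (median -2.91). The Wnt antagonist gene Sfrp1 fell by 3.66, the retinoic acid binding gene Crabp2 by 3.57 and the insulin-like growth factor binding gene Igfbp5 by 3.55, while of 6 imprinted growth genes Cdkn1c and Dlk1 rose by 1.92 and 1.14 and H19 fell by 3.26 (median -0.32, but 0.41 with TMM). The median gene fell by 0.74 (by 0.61 with equal weight for every cell) and TMM scaling would add 0.73, so smaller falls are not particular to a gene. Acta2, Myl9, Tagln, Tpm2, Col4a1, Col4a2 and H19 were over 3 times higher in another class of the E16 library and are read with that limit, and Prb1 shares 55.1% of its 3' sequence with other genes and is uncertain.

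**Figure D2:**
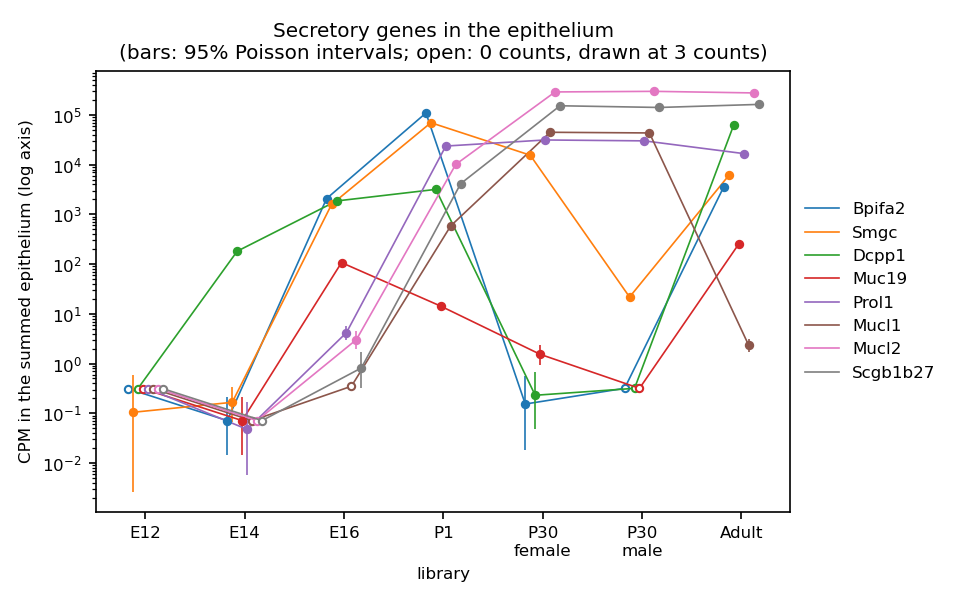
CPM in the summed epithelium (vertical log axis) of 8 secretory genes (lines) in the 7 libraries (horizontal axis), with bars for 95% Poisson intervals and open symbols at the level of 3 counts where the count was 0. Bpifa2 peaks at P1 (109730 CPM), and Mucl2 is the highest gene from P30 females (290990 CPM) on.

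From P1 to P30, the salivary products were exchanged. Bpifa2 went from 4419563 counts to 2 in P30 females (log2 -19.45, -22.50 to -17.60) and to 0 in P30 males. With that 0 set to 3 counts Bpifa2 was 346300-fold lower in males, and at least 281600-fold lower by the interval. Dcpp1 fell by 13.76 in P30 females (-11.09 with equal cell weight) and to 0 counts in P30 males, 10060-fold lower with the 0 set to 3 counts. The proline-rich protein gene Prpmp5 was at 0 in both, 2508-fold and 1819-fold lower at the same floor. The mucin-like genes Mucl1 and Mucl2 rose by 6.25 and 4.85 in P30 females, and the secretoglobin genes Scgb2b26, Scgb1b27 and Scgb2b27 rose by 5.48, 5.21 and 4.55. Over all P30 female barcodes before filtering, Mucl2 alone made up 24.8% of the counts. The 10 most abundant genes, among them the globin genes Hba-a1 and Hbb-bs at 4.29% and 4.03%, made up 71.2%. Of 13 secretory products, 6 were higher and 5 lower in each sex, with medians of 0.41 (-8.36 to 4.55) in females and 0.35 (-11.65 to 4.40) in males, though with equal cell weight 4 were higher and 4 lower in females and 5 and 6 in males. With TMM, 7 were higher and 3 lower in females (median 1.76) and 8 and 4 in males (median 1.76). Genes of the granular convoluted tubule, a duct segment that secretes kallikreins, rose in both sexes, 6 of 6 in females (median 4.93) and 14 of 14 in males (median 7.62), with Klk1b26 up by 8.47 and 10.90 (9.29 and 12.12 with equal cell weight). Tubule genes far below 50 CPM at P1, such as Klk1b26 at 0.199 and Klk1b9 at 7.99, entered only through their P30 level. Their direction and the counts of 6 of 6 and 14 of 14 follow from this filter, and the 2 medians cover different sets of genes. Imprinted growth genes fell together, 4 of 4 in each sex (medians -7.06 and -8.02, with equal cell weight -5.00 and -6.25), with Dlk1 at -10.26 and Cdkn1c at -6.39 in females (-7.93 and -4.54 with equal cell weight), while Peg3 and Meg3 were over 3 times higher in another class of the P1 library. The 3 expressed cell cycle genes, Mcm6, Ube2c and Hmgb2, fell in both sexes (medians -3.47 and -4.67, with equal cell weight -3.30 and -2.53). Imprinted growth and cell cycle genes far below 50 CPM at P30 likewise entered only through their P1 level, so their direction follows from the filter. The median gene fell by 1.55 in females and 1.63 in males, but by 0.47 and 0.54 with equal cell weight, and TMM scaling would add 1.35 and 1.41. The secretory machinery medians were -1.53 and -1.46, with equal cell weight -1.07 and -0.98 and with TMM -0.18 and -0.04, so whether this list moved apart from the median gene depends on the scaling.

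At P30 the 2 sexes were compared, since the mouse submandibular gland is known to differ between them after puberty. All 14 expressed granular convoluted tubule genes were higher in the male epithelium, with a median log2 ratio of 2.91 (2.21 to 3.47) and percentile 100 among 10000 random lists matched on expression. Those under 50 CPM in females, such as Klk1b3 at 37.8, entered only through their male level. That they were higher follows from this filter, which also limits the percentile. Klk1b9 and Klk1b16, at 104 and 52.9 CPM in females, passed the minimum in both sexes. The kallikrein genes Klk1b3, Klk1b9 and Klk1b27 were higher by 3.61, 3.47 and 3.23. Smgc was lower in males by 9.48 (-9.68 to -9.28), at 21.8 CPM against 15531. Among the largest differences of single genes were St3gal1 lower in males by 5.47, St3gal4 by 3.12, and St6galnac2 higher by 6.36 (5.42 to 7.49). Gcnt1 was at 0 counts in males, 161-fold lower with the 0 set to 3 counts (a log2 ratio of -7.33), and at least 130-fold lower by the interval. With equal weight for every cell, Gcnt1 was at -5.99, St3gal1 at -3.28 and St6galnac2 at 3.29. Krt14 and Sfn, the 2 expressed basal genes, were lower in males (median -2.14), while of 10 secretory products (median -0.01) Smgc was the 1 lower, and the others changed by under 2-fold, except that Pip was higher by 1.29 when every cell had equal weight. The male library held 400 epithelial cells and the female 484, the median gene moved by -0.05 and TMM scaling would add 0.07. The kallikrein genes sit together on chromosome 7 and share up to 61.6% of their 3' sequence, so the single values are uncertain.

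**Figure D3:**
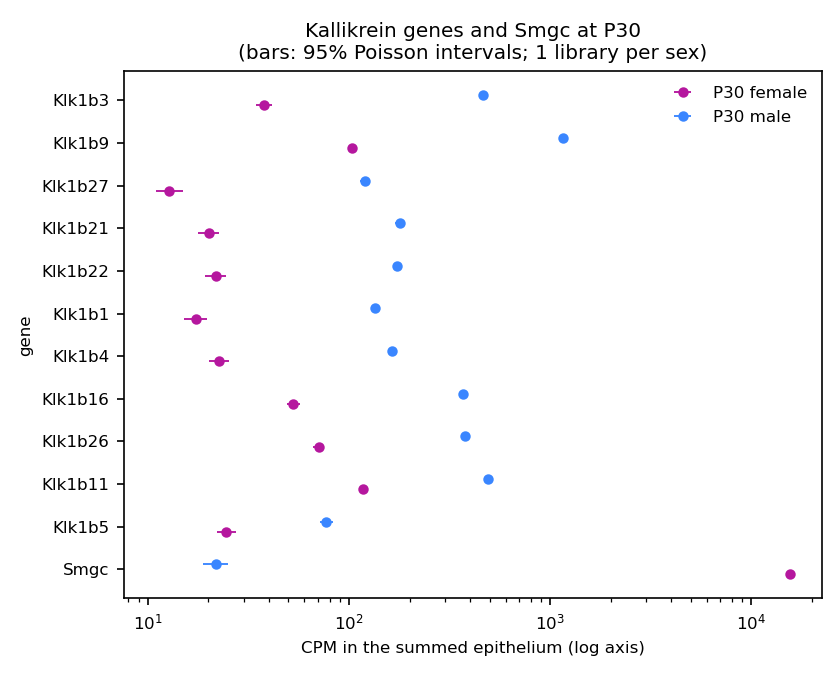
CPM in the P30 epithelium (horizontal log axis) of the expressed kallikrein genes of the tubule list and of Smgc (vertical axis) in females and males (colours), with bars for 95% Poisson intervals. All kallikrein genes drawn lie higher in males and Smgc lies higher in females.

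Between P30 females and adults, the products moved apart again, over a step that also changes strain. Dcpp1, Dcpp2 and Dcpp3, which lie side by side on chromosome 17, reached 63971, 63088 and 10426 CPM in adults from 3, 0 and 0 counts, with a log2 ratio of 18.09 (16.54 to 20.36) for Dcpp1, or 15.23 with equal cell weight. Bpifa2 rose by 14.54, Muc19 by 7.38 and the urinary protein gene Mup4 by 9.80 (11.98 with equal cell weight), while Mucl1 (chromosome 15, 103751919 to 103755469) fell from 44904 to 2.32 CPM (log2 -14.24, -14.70 to -13.82). Of 16 secretory products, 6 were higher and 3 lower (median 0.10, -0.97 to 14.54), while with TMM or equal cell weight 7 were higher and 0 lower. Of 6 tubule genes, 4 were lower (median -1.56), but 2 with equal cell weight (median -0.83), with Egf, the epidermal growth factor gene, down by 1.88 and Klk1b26 by 1.99. Duct keratin and junction genes fell as well, 6 of 9 being lower (median -1.53), with Elf3, Cldn4 and Krt8 down by 2.23, 2.05 and 1.80. Acta2 rose by 2.49, and the heat shock genes Hspa1a and Hspa1b by 2.73 and 3.25. The median gene fell by 0.53 (-0.09 with equal cell weight) and TMM scaling would add 0.51, and the Dcpp genes share 41.4% to 45.3% of their 3' sequence. Like Bpifa2, Hspa1a and Hspa1b, they were over 3 times higher in another class of the adult library.

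Shares of cells with at least 1 UMI were taken with every cell thinned to 1000 UMIs. Among epithelial cells, Mki67, a marker of dividing cells, was seen in 8.41% at E12, 6.77% at E14, 4.40% at E16, 2.35% at P1, 0.207% in P30 females, 0 of 400 cells in P30 males (which allows up to 0.918%) and 0.125% in adults. Top2a, also of dividing cells, was seen in 19.4%, 16.4%, 9.76%, 3.28%, 0.620%, 0.25% and 0.251% in that order. At 1500 UMIs it was seen in 21.9% at E12 and 23.9% at E14, and the intervals of E12 and E14 overlapped at 1000 and at 1500 UMIs. The background class, mesenchyme to P1, immune cells at P30 and endothelium in adults, divides too, and its Mki67 share was 4.27%, 2.93%, 6.28%, 2.14%, 3.81%, 2.04% and 1.16%. Median depths were 17467, 14713, 8523, 11962, 6993, 6524.5 and 2577 UMIs in epithelium against 6228, 5196, 5955, 5488.5, 4805, 4361 and 937.5 in the background class. In adults, 302 epithelial and 120 endothelial cells had under 1000 UMIs and were left out.

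Smgc was seen in 0 of 511 epithelial cells at E12 (up to 0.719%), 0.0716% at E14, 17.1% at E16, 87.0% at P1, 44.4% in P30 females, 1.75% in P30 males and 27.4% in adults. Its background share was 0, 0, 0.592%, 76.0%, 10.5%, 0 and 16.3%. Bpifa2 was seen in 0%, 0%, 17.02%, 96.2%, 0%, 0% and 16.5% of the epithelial cells, with 1.37% in the background class at E16, 98.8% at P1 and 9.30% in adults. The P1 Bpifa2 share did not exceed the background, and reads as free RNA of an abundant transcript. In amount the classes still differed, with 109730 CPM of Bpifa2 in the P1 epithelium against 4816 in the mesenchyme, and 69980 against 1633 for Smgc. Both genes were seen together in 3.21% of epithelial cells at E16 (background 0%), 83.6% at P1 (background 74.8%) and 3.76% in adults (background 1.16%), and in 0% elsewhere.

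Krt14, a basal and myoepithelial keratin gene, was seen in 21.7%, 27.6%, 25.2%, 9.60%, 3.10%, 0.75% and 10.3% of epithelial cells from E12 to adults, with background shares between 0% and 1.68%. Acta2, of smooth muscle and myoepithelial cells, was seen in 0.587%, 4.05%, 25%, 3.59%, 0.620%, 1.50% and 3.45%, with 4.33% of mesenchyme at E16 and 2.62% at P1. Aqp5 was seen in 0% at E12, 0.465% at E14, 14.8% at E16, 31.2% at P1, 21.3% in P30 females, 14% in P30 males and 13.03% in adults, with background shares between 0% and 1.67%. The receptor gene Kit was seen in 0.196%, 1.25%, 1.55%, 1.76%, 0.413%, 0% and 1.25%, with background shares between 0% and 0.476%. Ascl3, a transcription factor gene of a duct cell type, was seen in 0%, 0%, 0.476%, 0.380%, 1.65%, 2.00% and 2.44%, with background shares of 0.476% at P1 and 0.680% in P30 males.

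In the mesenchyme, matrix genes rose from E12 to E14. Mfap5, a microfibril gene (chromosome 6, 122505845 to 122529290), rose by 3.89 (3.73 to 4.06) and the proteoglycan gene Dcn by 2.01 to 2224 CPM. Of 16 fibrillar matrix genes, 8 were higher and 0 lower, with a median of 1.04 (0.73 to 1.34; 12 higher with TMM), among them Col6a2 by 1.55 and Col1a1 by 1.34. Among the largest falls were Nnat, down by 4.54, the ligand gene Tgfb2 by 3.26 and the transcription factor gene Ebf2 by 2.90. The patterning factors were mixed, with Prrx2 up by 1.50 and Pitx1, of jaw mesenchyme, down by 1.18 (-0.96 with TMM, under 2-fold), and Kitl, which encodes the ligand of the Kit receptor, rose by 2.98. Of 16 stress genes, 8 were higher (median 1.02), with Hspa1a up by 4.44 and Atf3 by 3.18. No cell cycle gene of 22 changed by 2-fold (median -0.55). The sums came from 4024 and 1841 cells, the median gene moved by -0.10 and TMM scaling would add 0.22.

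From E14 to E16 the mesenchyme gained more matrix and more transcripts of dividing cells. Fibrillar matrix genes had a median of 1.10 (0.63 to 1.38), 11 of 20 being higher, with Thbs2, Col14a1 and the elastin gene Eln up by 2.55, 2.34 and 2.31. Nov, a matricellular gene (chromosome 15, 54745702 to 54754039), rose by 7.64 (6.28 to 9.52), and the fibroblast genes Clec3b and Dpt by 4.74 and 4.15. Of 24 cell cycle genes, 17 were higher (median 1.14, 0.86 to 1.45), such as Ccnb2, Ccna2 and Rrm2. Of 8 basement membrane genes, 4 were higher (median 0.93), with the nidogen gene Nid1 up by 1.71, while the other 3 (Hspg2, Col4a1 and Col4a2) were over 3 times higher in another class of the E16 library. Of 8 patterning factors, 3 were lower and 0 higher (median -0.54, -1.89 to 0.14), Pitx1 by 1.89, Osr1 by 1.53 and Barx1 by 1.07, the last just under 2-fold with TMM. The retinoic acid binding gene Crabp2 fell by 3.87 and the calcium-regulated factor gene Nfatc2 by 3.54. Of 17 stress genes, 4 were lower and 1 was higher (median -0.39, -0.93 to 0.33), with Hspa1a down by 2.14. The sums came from 1841 and 2196 cells, the median gene moved by -0.06 and TMM scaling would add 0.07.

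From E16 to P1, cell cycle genes fell in the mesenchyme and a part of the matrix genes rose. The cell cycle list fell by 2.08 in its median (-2.96 to -1.56), with 22 of 24 genes lower, such as Plk1 by 3.88 and Cenpf by 3.20. Fibrillar matrix genes had a median of 0.62 (0.36 to 0.96), 5 of 20 being higher (4 with equal cell weight), with Postn up by 1.33, Col6a2 by 1.22 and Dcn by 1.07. Of 10 basement membrane genes, 4 were higher (median 0.97; 6 with TMM and 3 with equal cell weight), among them Col4a1 by 1.59 and Lamc1 by 1.56. The ceruloplasmin gene Cp rose by 6.47, the chemokine gene Ccl2 by 4.62, the metallothionein genes Mt2 and Mt1 by 3.86 and 3.38 and the matrix Gla protein gene Mgp by 3.30. Of 5 antigen presentation and interferon genes, 4 were higher (median 1.36), although 3 of these, H2-K1, H2-D1 and Bst2, were over 3 times higher in another class of the P1 library. Salivary genes such as Mucl2, Prol1 and Car6 also rose in the mesenchyme (9 of 9 secretory products, median 10.58), where they were far below the epithelial level and read as free RNA. The P1 sum came from 420 cells, the median gene moved by -0.25 and TMM scaling would add 0.12.

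The globins of erythroid cells marked the age of the blood. Embryonic globins (Hba-x, Hbb-y and Hbb-bh1) were 58.7% of the globin counts of the 59 erythroid cells at E12 (58.6 to 58.8), with Hbb-y (chromosome 7, 103851749 to 103853216) alone at 51.3%. They were 6.34% in 240 cells at E14 (6.30 to 6.38) and 0.00196% in 747 cells at E16 (0.00158 to 0.00240), against 0.0164% over all barcodes with mostly globin counts. At P1 they were 0 of the globin counts of all cells (up to 0.00391%), and 0 in 37 erythroid cells of P30 males (up to 0.00112%) and in all adult cells (up to 0.0112%). In P30 females, over all cells, 46 counts of Hbb-bh1 made 0.0342% (0.0251 to 0.0456), against 0.00321% over the barcodes with mostly globin counts. The adult globins Hbb-bs and Hba-a1 made up 49.5% and 32.7% at E16.

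**Figure D4:**
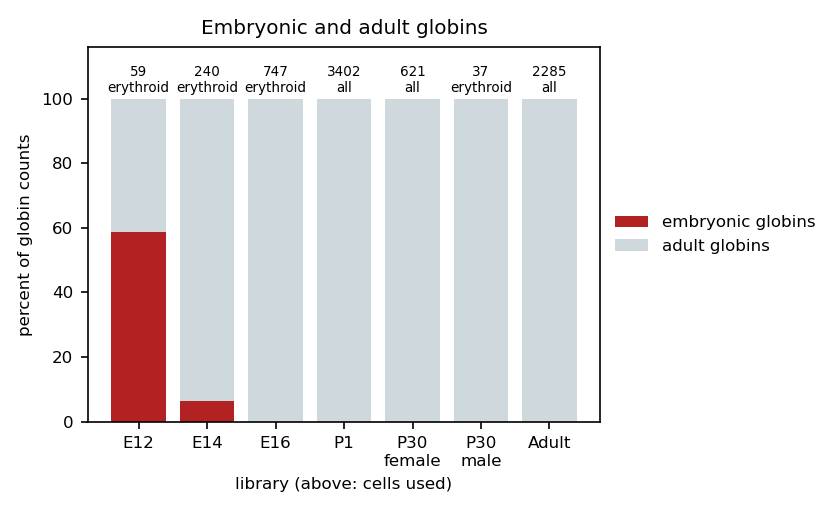
Percent of globin counts from embryonic and from adult globin genes (vertical axis, stacked bars from 0 to 100) in the erythroid cells, or in all cells where these were under 20, of the 7 libraries (horizontal axis). The embryonic part falls from 58.7% at E12 to 6.34% at E14 and is 0.0342% or less in the later libraries.

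Transcripts that tell sexes apart matched the labels. Xist, expressed from the inactive X chromosome, had 264 CPM in P30 females and 0 counts in P30 males, and Ddx3y, on the Y chromosome, had 12.9 CPM in P30 males and 0 counts in P30 females. The adult cells had 200.3 CPM of Xist and 0 counts of Ddx3y, Eif2s3y, Uty and Kdm5d. The E12, E14, E16 and P1 libraries had counts of both Xist and Ddx3y, from pooled littermates.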

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

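No test was run on the results in this part, and the measure of mostly globin barcodes was chosen after the data were seen. From E16 to P1, some of the named genes moved in opposite directions in epithelium and mesenchyme, and 4 of them are given here. Col4a1 also fell in epithelium and rose by 1.59 in mesenchyme. It is not among the 4, and it was far higher in another class of the E16 library than in epithelium. Igfbp5 had a log2 ratio of -3.55 in epithelium and 1.58 in mesenchyme, Ifitm3 -1.15 and 1.23, Nr4a1 -1.19 and 1.38, and Cdkn1c 1.92 and -1.25. The difference between the classes was not tested, since each class has 1 library per age. TMM scaling would add 0.73 in epithelium and 0.12 in mesenchyme. With it, the epithelial values of Ifitm3 and Nr4a1 become -0.42 and -0.46, under a 2-fold fall, while Igfbp5 and Cdkn1c keep a change of over 2-fold in both classes. No explanation was tested for this pattern.

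Barcodes with under 200 detected genes were not used in the comparisons, and in 6 libraries more than 3 of them held mostly globin counts, which says only that such barcodes were present. They were 30.9% of all E16 barcodes, 24.6% in P30 females, 30.4% in P30 males, 7.87% in adults, 1.38% at P1 and 0.404% at E14. At E12 there was 1 such barcode, 0.0170% of all. Their median was 4839 UMIs at E16, 5706 in P30 females, 6229.5 in P30 males and 1835 in adults, against 5823, 5956.5, 5475.5 and 1573 over all barcodes of these libraries. It was further below the library at E14 (4307.5 against 8169.5) and P1 (5283 against 10707), and the E12 barcode had 5216 UMIs against 7036. The E16 share of erythroid cells in the report (14.1%) does not count these barcodes. No explanation was tested for the difference between libraries.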

How the results depend on the processing

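Among the alternatives here, counting unnamed clusters in their best-scoring class and taking all mostly globin barcodes were tests chosen after the result was seen, and the counting interval for a list with 1 gene was set after the first labels were seen. No list median with an interval that leaves out 0 changed sign under the alternatives run for it, and no named gene did under TMM or equal cell weight, the 2 run for genes. Medians with an interval across 0 changed sign in 7 values, as given below. Numbers of genes at 2-fold or more under these 2 scalings, given in the report, were counted after the data were seen and by value alone. The epithelial share moved beyond its interval in 9 of 35 values and kept the order of E12, E14, E16 and P1 under each alternative. With at least 500 genes it was 47.5% at E14, 17.8% at E16, 71.0% in P30 males and 79.1% in adults, without doublet removal 43.5% at E14 and 80.6% in adults, at resolution 0.5 72.0% in P30 females and 80.2% in adults, and with up to 20% mitochondrial counts 84.7% in adults. The cause was not tested.

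Of the medians of secretory products, fibrillar matrix and granular convoluted tubule genes, 1 moved, that of secretory products from E12 to E14, at 3.97 with no CPM minimum against 9.18, where 6 genes rather than Dcpp1 alone enter. By the order-statistic interval, which has no width for 1 gene, 7 of its 8 values would have moved. From P1 to P30 the secretory products have no firm direction, with medians of -0.23 for equal cell weight in females, and -1.65 and -1.53 with no CPM minimum in females and males, but of 1.76 in each sex with TMM. The other list medians kept their sign except the cell cycle from E12 to E14 in epithelium and the secretory products between sexes, both near 0, and the 6 imprinted growth genes in epithelium from E16 to P1, at 0.41 with TMM against -0.32. TMM scaling moved 8 of 40, among them the secretory machinery from P1 to P30, to -0.18 in females and -0.04 in males. All 174 values of named genes kept their sign under TMM and under equal weight, and of 173 at 2-fold or more, 168 and 172 stayed so. The exceptions under TMM were Ifitm3 (-0.42), Nr4a1 (-0.46) and Pdia4 (-0.99) in epithelium from E16 to P1. In mesenchyme they were Pitx1 from E12 to E14 (-0.96) and Barx1 from E14 to E16, which fell just short of 2-fold. With equal weight, Nr4a1 was also under 2-fold (-0.97). Equal weight moved 18 of the 174 by more than 1 on the log2 scale, 16 of them nearer to 0, so the size of these changes is less firm than their sign. They were Col2a1 from E14 to E16 (-7.47), then from P1 to P30 females Dcpp1 (-11.09), Dlk1 (-7.93), Meg3 (-5.45), Cdkn1c (-4.54), Peg3 (-2.47) and Hmgb2 (-1.77), and from P1 to P30 males Klk1b26 (12.12), Meg3 (-5.61), Peg3 (-3.57), Mcm6 (-2.89), Ube2c (-2.53) and Hmgb2 (-1.52). Between sexes they were Gcnt1 (-5.99), St3gal1 (-3.28) and St6galnac2 (3.29), and between P30 females and adults Dcpp1 (15.23) and Mup4 (11.98).

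Some numbers of list members at 2-fold or more also differ by scaling where the report gives 1 number. In epithelium with TMM, 4 imprinted growth genes were lower from E12 to E14 and 1 end bud regulator was higher. From E14 to E16, 9 duct keratin and junction genes were higher and 1 lower, 3 duct ion transport genes and 8 stress genes were higher, and 0 end bud regulators were higher. From E16 to P1, 13 secretory products were higher, and 4 contractile genes and 2 basement membrane genes were lower. Between P30 females and adults, 3 tubule genes and 5 duct keratin and junction genes were lower. In mesenchyme with TMM, 9 stress genes were higher from E12 to E14, 12 fibrillar matrix genes were higher from E14 to E16, and from E16 to P1 6 fibrillar matrix genes and 5 antigen presentation genes were higher and 21 cell cycle genes lower. With equal cell weight, in epithelium 4 imprinted growth genes were lower from E12 to E14. From E14 to E16, 10 stress genes were higher, 4 end bud regulators and 1 secretory machinery gene were lower and 0 end bud regulators were higher. From E16 to P1, 12 secretory products and 4 secretory machinery genes were higher, and 17 cell cycle genes and 4 contractile genes were lower. Between P30 females and adults, 5 duct keratin and junction genes were lower, and in mesenchyme 9 fibrillar matrix genes were higher from E12 to E14.

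Depth limits the shares of cells with a UMI, which are given in the order E12, E14, E16, P1, P30 females, P30 males, adults. Thinned to 1500 UMIs, Mki67 was seen in 10.8, 9.77, 7.38, 3.04, 0.207, 0 and 0.3701 percent, and Top2a in 21.9, 23.9, 12.5, 4.32, 0.6198, 0 and 0.222 percent. Smgc was seen in 0, 0, 16.9, 93.2, 48.8, 2.25 and 28.4 percent, and Bpifa2 in 0, 0, 17.7, 99.2, 0, 0 and 20.5 percent. Krt14 was seen in 26.4, 38.3, 31.9, 11.1, 4.34, 0.75 and 10.4 percent, and Acta2 in 0.783, 5.51, 26.8, 3.903, 0.826, 1 and 3.405 percent. Kit was seen in 0.978, 1.32, 1.905, 2.69, 1.86, 1 and 1.702 percent, and Aqp5 in 0, 0.6803, 19.05, 38.5, 26.03, 19.2 and 17.5 percent. Ascl3 was seen in 0, 0.0358, 0.714, 0.345, 1.86, 3.5 and 1.26 percent, and Smgc and Bpifa2 together in 0, 0, 2.74, 92.4, 0, 0 and 5.699 percent. Of 27 values that moved, 24 were higher, and in adults the deeper thinning left out 547 cells rather than 302. Without thinning, Mki67 was seen in 55.8, 53.02, 31.8, 15.1, 2.07, 0.5 and 0.843 percent, and Top2a in 64.6, 66.6, 33.5, 19.3, 1.65, 1.75 and 0.738 percent. Smgc was seen in 0.196, 0.215, 23.9, 100, 80.6, 5.75 and 44.9 percent, and Bpifa2 in 0, 0.107, 25.5, 100, 0.413, 0 and 28.2 percent. Krt14 was seen in 75.9, 82.5, 47.1, 17.7, 5.99, 1.25 and 11.7 percent, and Acta2 in 9.98, 24.1, 34.5, 9.603, 1.45, 3 and 4.32 percent. Kit was seen in 11.3, 12.3, 15.2, 16.9, 5.37, 2 and 3.16 percent, and Aqp5 in 0, 6.23, 45.8, 74.1, 61.8, 43.8 and 42.3 percent. Ascl3 was seen in 0, 0.0716, 1.55, 0.725, 3.31, 5 and 3.53 percent, and Smgc and Bpifa2 together in 0, 0, 7.98, 100, 0.413, 0 and 14.3 percent. All 50 values that moved were higher, and unequal depth between libraries enters them. The fall of Mki67 from E12 to P1 held at each depth. Top2a was lower at E14 than at E12 at 1000 UMIs but higher at 1500 UMIs and without thinning. The intervals of E12 and E14 overlapped at each depth, so no direction is read over that step.

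With all mostly globin barcodes the embryonic globin share was 57.97% at E12, 6.14% at E14, 0.0164% at E16 and 0.00321% in P30 females. The order of E12, E14 and E16 held, and the cause of the higher E16 value was not tested. Among the other class shares, 18 of 55 values moved. Genes under 50 CPM were not ranked, so changes of weakly expressed genes are not covered.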

Other observations

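Of the tests in this part, all except the comparison of Dcpp1, Dcpp2, Dcpp3 and Muc19 between adult epithelium and adult immune cells were chosen after the result was seen.

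The 10 largest falls in epithelium from E14 to E16 included genes that share sequence with near-identical copies. Their median shared 3' sequence was 44.3%, above all random gene sets of like expression (median 0), and 7 of the 10 shared at least 10%, against 18.4% of 4753 genes. Shared reads may therefore play a part in the values of Hist1h2ap, Gstp1, Pgk1 and Eno1, although genes sharing at least 40% had a median log2 ratio of -0.18, close to -0.14 for the 2503 genes sharing under 10%, which argues against a general effect. The other 3, Sf3a2, Hmga2 and Col2a1, share at most 1.10% and fell by 3.51, 4.34 and 8.93, and no explanation by sequence was tested for them. The same 10 genes also fell in the E16 mesenchyme, with a median of -2.71 (-3.87 to -1.70), although Fabp5 rose there by 0.27. In endothelium and immune cells all 10 ratios were negative, with medians of -2.71 and -2.35, though the E14 endothelium had 32 cells and Hmga2 in immune cells (-0.49, -1.51 to 0.61) has an interval across 0. An effect on all cells of the E16 library may therefore contribute as well. A change of the gland between E14 and E16 stays open and was not tested, since stage, dissociation and library change together.

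Within the adult epithelium, Dcpp1, Dcpp2, Dcpp3 and Muc19 came from few cells. The 2 clusters led by these genes, with 233 of the epithelial cells, held 98.2% of the epithelial counts of Muc19 and 99.3% of the epithelial counts of Dcpp1. With these clusters left out, the median ratio of the 4 genes in the other 1665 epithelial cells to adult immune cells was 0.265, with an interval up to 1.79 for Muc19. As the clusters left out are those led by the tested genes, a low value follows from that choice, and cells of another gland in the preparation cannot be told apart from a small group of cells of the gland itself. Reads shared among the 3 Dcpp genes are not the whole cause, as their summed CPM still rose by 19.19 on the log2 scale. Each of the 4 genes had at least 14.25 CPM in P1 epithelium, also of ICR mice, although the Dcpp genes share 3' sequence. This argues against a variant of all ICR mice that hides the genes fully. It cannot exclude a variant of the P30 mice alone, or one that hides a part of the reads. Strain and age change together between P30 females and adults and stay open, and which software version served the P30 libraries is not given in the sources used here.

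At P30, granular convoluted tubule genes were higher and Smgc was lower in males. A larger share of striated or excretory duct cells does not account for the whole difference in the tubule genes. The 4 markers of these ducts had a median log2 ratio of 0.52 (range -0.20 to 1.21) against 2.91 for the tubule genes. A larger share of tubule cells need not raise these markers, so the values cannot decide on it. A mislabelled sample is argued against by 0 counts of Xist in males and 0 of 4 Y-linked genes in females, beside 3650 and 353 counts in the other sex. Whether the cells with Smgc were missed in the male library cannot be told apart from a lower Smgc level in them, as 8 other leading genes of the P30 female Smgc cluster had a median of -1.59 with members from -6.51 for Fgg to 0.45 for Agr2. A difference between the sexes stays open as a hypothesis, with 1 library of each.

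Other values describe single clusters, which were not compared between libraries. Clusters with Ascl3 among their top genes had 26 cells in P30 females, 33 in P30 males and 73 in adults. Clusters of high depth were seen among P30 female epithelial cells, with 62 cells at a median of 93817 UMIs and 24 cells at 67822.5, and in adults with 418 cells at 23706. The cells of such epithelial clusters are part of the epithelial sums, in which deep cells weigh more than others. The P30 male epithelium held a cluster of 23 cells led by kallikrein genes such as Klk1b26 and Klk1b27. Adult epithelium held a cluster of 65 cells with Acta2 and Cnn1 among its top genes, and 2 with Smgc at the top, of 248 and 90 cells.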
